A study of Mus musculus with 12 samples.

How the data were processed

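Polyadenylated RNA of 12 BALB/c mouse liver samples was measured, 3 in each of 4 groups, with a stranded Illumina mRNA kit after TRIzol extraction, per the labels' protocols. The authors deposited raw counts per gene symbol, whole numbers with no normalization. A second table deposited by the authors holds a normalized signal, which by its values is the raw count divided by 1 factor per library, and it was used only for that check. TopHat and Cufflinks are named without version or role, per the submitters' processing notes. The genome build, the annotation, the counting tool and whether counting used strand are not given in the sources used here, so no positions are printed. Reads of antisense or overlapping genes could not be told apart if strand was ignored, and levels of close paralogs and pseudogenes are uncertain. Of 25540 symbols, 21245 were found among current RefSeq symbols and 23773 in GENCODE, and symbols are printed as deposited.

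All 12 libraries entered 1 edgeR fit (version 4.0.16, R 4.3.3) with a term per group, TMM scaling and edgeR's filter by group (minimum count 10, minimum total 15). This kept 15720 genes and removed 9820. The robust quasi-likelihood F test was used with Benjamini-Hochberg adjusted p under 0.05, 8 residual degrees of freedom and a biological coefficient of variation of 0.247. The SE of a log2 fold change is its size divided by the square root of F. Levels are CPM on TMM-scaled totals. TMM factors lay between 1.11 and 1.27 in the controls and between 0.804 and 0.901 in the libraries labelled STAT3. Depth was 39844158 to 67791159 counts per library. Counting intervals are 95% and cover counting error only, as does the floor of 3 counts over a group used for genes with a count of 0.

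The comparisons were each STAT3 group with its control, the difference of these 2 changes, and the 2 controls. Comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The comparison of the 2 STAT3 groups, the mean of both arms, the test of lists on the difference of the arms, scaling by library totals, thinning all libraries to the smallest total and the splits within both arms were added after the data were seen. The named genes are Stat3, and in each arm the 10 highest and 10 lowest log2 fold changes among genes that passed, had a mean of at least 1 CPM and did not overlap between groups, which 3099 higher and 2936 lower genes did in the siRNA arm and 2959 and 3002 in the mASO arm. For the difference of the arms and for the controls the 5 highest and 5 lowest were taken, and the condition on overlap was dropped for the difference, where it is undefined. From each list up to 4 members with the smallest p and the members that passed over the list alone could be named. Among these, the examples printed were picked after their values were seen, for calls that held under the alternatives, and exceptions are given with their values.

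Of 36 fixed gene lists, 34 with at least 5 measured members were tested with limma's camera (version 3.58.1) on voom values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 34. Camera with an estimated correlation and limma's fry, which tests whether a list's genes move one way on balance, were run beside it. Counts of members adjusted over the list alone use the same edgeR p-values. The lists cover liver cell types, hepatocyte functions and zones, lipid and glucose metabolism, matrix, inflammation, STAT3 signalling, stress, cell cycle, clock and RNA machinery. Some genes stand in more than 1 list, such as Acta2 and Tagln in the matrix and stellate lists, so lists are not independent. One drug-metabolism gene, Cyp3a41a, and Cxcl2 in the siRNA arm had 3 or fewer counts in a group, and list medians were the same with them at the floor. Alternatives were DESeq2's size factors, its Wald test (version 1.42.0), limma voom, no filter, a stricter filter of 1 CPM in 3 libraries, a block for the replicate number, a fit over the compared libraries alone and leaving out each library. Residual correlations of libraries with the same number ran from −0.110 to 0.187, so the numbers were not taken to pair libraries.

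The procedure was tested on simulated counts of the real genes with 200 genes changed. Simulated means followed library totals, with no composition shift. False calls with as many changed genes or as uneven TMM factors as in the real arms were therefore not tested. For the siRNA arm, over 15477 genes, edgeR recovered 61.2% of changes of size 1 and 77.0% of size 2 on the log2 scale, with 4.86% false among 144 calls. For the mASO arm, over 15431 genes, it recovered 50% and 75.8%, with 7.46% false among 134 calls. Camera called 0 of 30 unchanged simulated lists in either arm, with members simulated as uncorrelated. Libraries of a group were checked for duplication, and the chi-square per degree of freedom between pairs ran from 52.6 to 222, far above 1. Xist had 14437 to 31785 counts in the 12 libraries and the Y-linked gene Ddx3y 0 to 1. Other splits of the samples were refitted for counts of genes or lists, all 10 splits for 3 against 3 libraries and 50 splits, the real one included, where more exist. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.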

Results

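Liver mRNA was sequenced from 12 BALB/c mouse samples in 4 groups of 3. The labels name each group after an injected preparation called iExos, taken here as exosomes from the title of the series. Exosomes are small vesicles that cells release. The preparations carried siCntrl, siSTAT3, mASO Scrbl or mASO STAT3. The prefix si is the usual one for small interfering RNA (siRNA) and ASO for antisense oligonucleotide, while the meaning of the m in mASO is not given in the sources used here. Each STAT3 group was compared with the control of its own arm, and the arms, the controls and the STAT3 groups were then compared with each other. The title places the study in liver fibrosis and names STAT3, a transcription factor activated by interleukin 6, as the target. Libraries of uninjected or healthy livers were not analysed here, and the labels do not say whether the livers were injured.

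Library totals ran from 55406038 to 67791159 counts in siCntrl, 39844158 to 57926887 in siSTAT3, 64619765 to 66498894 in mASO Scrbl and 50024153 to 61804382 in mASO STAT3. The 10 most abundant genes held 18.01% ± 1.91 of the counts in siCntrl and 21.3% ± 0.775 in siSTAT3 (SD, n = 3), and 16.5% ± 2.09 in mASO Scrbl against 20.9% ± 2.12 in mASO STAT3. The first principal component of log2 CPM carried 63.5% of the variance and placed the 6 control libraries on one side of 0 and the 6 libraries labelled STAT3 on the other. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples, which may be technical. Gene levels below are means of CPM, counts scaled to the library total and its TMM composition factor, ± SD over the 3 libraries of a group, with the group labelled STAT3 first, and log2 fold changes are given ± SE. Where leaving out 1 library moved the fold change of a named gene by more than 1.5 times, its log2 fold change without that library closes the paragraph, and so do counts of list members that an alternative moved by more than 1.5 times and at least 2 members.

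Stat3, the named target, was reported first because its level would check the labels. In the siRNA arm Stat3 stood at 109.9 ± 16.2 CPM in siSTAT3 and 112 ± 7.501 CPM in siCntrl (SD, n = 3). In the mASO arm it stood at 103 ± 13.7 CPM in mASO STAT3 and 99.2 ± 8.40 CPM in mASO Scrbl. The 12 libraries held between 3967 and 8767 Stat3 counts each. By library, Stat3 was at 91.5, 116 and 122 CPM in siSTAT3, 106, 121 and 111 CPM in siCntrl, 105, 88.2 and 115 CPM in mASO STAT3, and 106, 89.96 and 101 CPM in mASO Scrbl. The log2 fold change was −0.03 ± 0.14 in the siRNA arm (95% interval −0.34 to 0.27, edgeR adjusted p = 0.868) and 0.05 ± 0.14 in the mASO arm (−0.25 to 0.36, edgeR adjusted p = 0.792). Exact two-sided permutation of the 6 log2 CPM values gave p = 0.9 and p = 0.8, and 0.1 is the smallest p that 3 libraries against 3 allow. Falls of Stat3 mRNA by more than 20.8% and 16.0% lay outside the intervals. Scaling by library totals alone gave −0.54 and −0.53 (edgeR adjusted p = 0.00446 and 0.00413), a scaling under which the median of all tested genes moved to −0.53 and −0.63, and changes are therefore reported relative to the composition-scaled level. Stat3 does not check which libraries received which load, and groups are named by their labels throughout.

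**Figure D1:**
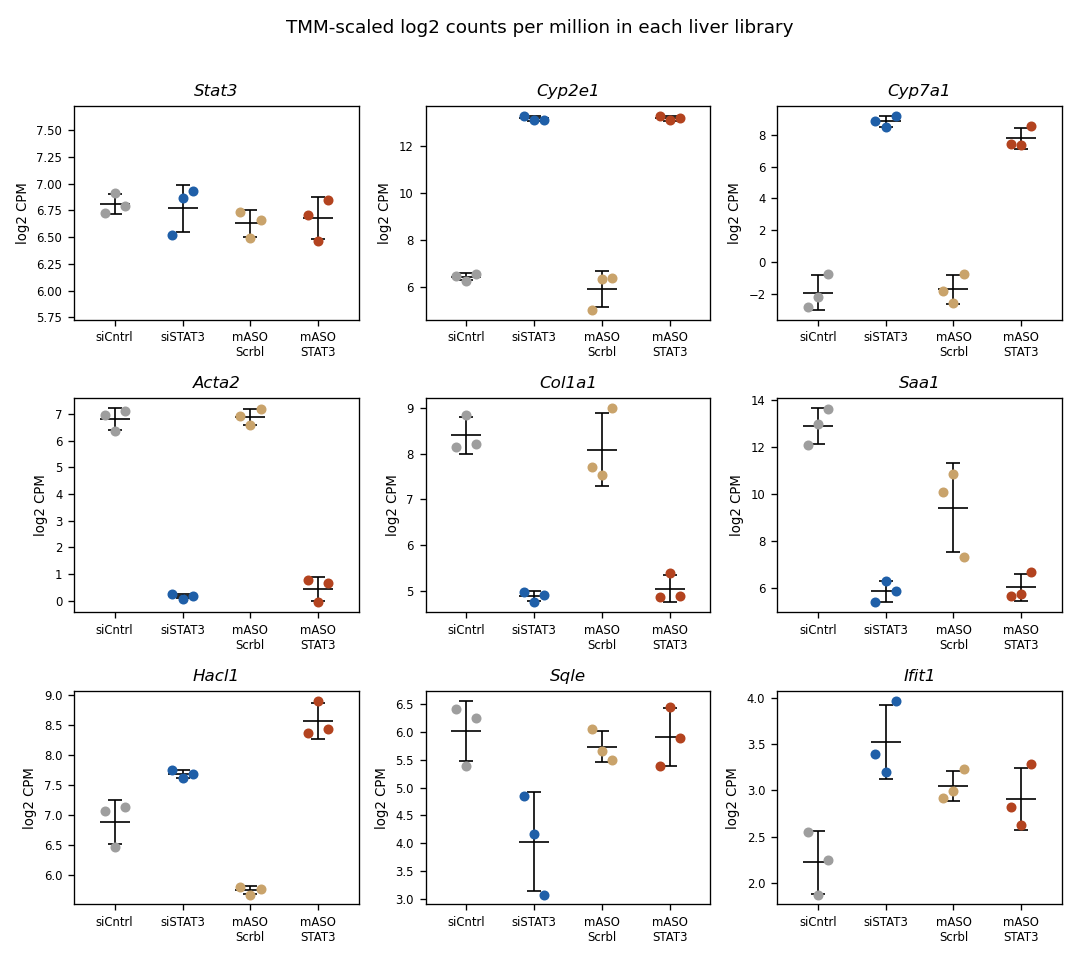
Log2 CPM of 9 genes in each of the 12 libraries, by group, with the mean and SD of 3 libraries as bars. Stat3 lies between 88.2 and 122 CPM in all 4 groups, while Cyp2e1 lies at 9380 and 9447 CPM in the groups labelled STAT3 and at 86.2 and 64.6 CPM in their controls.

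In the siRNA arm, livers labelled siSTAT3 carried more mRNA of most P450 and bile acid genes measured than siCntrl livers, and less of most extracellular matrix genes. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 467 ± 111 against 0.289 ± 0.250 CPM (SD, n = 3), a log2 fold change of 10.66 ± 0.70. Cyp2e1, a cytochrome P450 of hepatocytes around the central vein, stood at 9380.2 ± 607 against 86.2 ± 8.90 CPM, and Acta2, the smooth muscle actin of myofibroblasts, at 1.09 ± 0.0616 against 115 ± 29.9 CPM. By edgeR's quasi-likelihood test 3515 genes were higher and 3675 lower of 15720 tested, 1718 and 2242 of them by more than 2-fold. Together 45.7% of all tested genes were called, the share against which member counts of lists in this arm are to be read. Scaled by library totals, 1655 were higher and 7266 lower, so that 18.6% of the calls were higher in place of 48.9%. Because Stat3 itself was not called different at the composition-scaled level, these directions rest on the labels alone. Cyp7a1 was at 11.63 without siCntrl 3.

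The genes with the highest fold changes included Serpina6, which encodes corticosteroid-binding globulin (1425 ± 442 against 3.72 ± 0.933 CPM), the uridine phosphorylase gene Upp2 (1021 ± 156 against 2.63 ± 0.999 CPM) and Slc1a2, a glutamate transporter gene of pericentral hepatocytes (85.9 ± 15.8 against 0.455 ± 0.107 CPM). Hamp2, a hepcidin paralog, was at 354 ± 100.2 against 1.79 ± 1.12 CPM, the methyltransferase gene Inmt at 1078 ± 193 against 10.3 ± 6.69 CPM, and Cyp3a16 and Cyp2c54 had log2 fold changes of 7.13 ± 0.58 and 6.66 ± 0.69. At the other end, Lox, whose enzyme crosslinks collagen, fell from 13.9 to 0.0616 CPM, a log2 fold change of −7.84 ± 0.48. Saa2, an acute phase gene, had a log2 fold change of −8.16 ± 1.08, and Sprr1a one of −8.27 ± 0.96. No count of Cdh17, Ctsj, Gdpd2 or Gml was seen in the siSTAT3 libraries. Taking 3 counts over the group as the floor, they were at least 215, 113, 95.5 and 90.1-fold lower. With 1 count in the group, the ratio was 504 for Gm8818 (counting interval 90.2 to 19926), 261 for 1700016C15Rik (46.6 to 10317) and 239 for Cxcl2, a neutrophil chemokine gene (42.6 to 9454). By the rule for named genes all 20 had to pass edgeR's test, and their adjusted p ran up to 2.11e-04. Without siSTAT3 1 the bounds were 128, 67.5, 56.8 and 53.6-fold and the ratios 299.7 (53.7 to 11851) for Gm8818 and 142 (25.4 to 5623) for Cxcl2, and 1700016C15Rik, with no count left, was at least 51.7-fold lower. Without siSTAT3 3 no count of Gm8818 or Cxcl2 was left, and they were at least 122 and 58.0-fold lower. Without siCntrl 2 the bound of Gdpd2 was 51.8-fold, and without siCntrl 3 the ratio of Cxcl2 was 119 (21.0 to 4722). Levels of close paralogs such as the Cyp2c, Cyp3a, Saa, Hamp and Sprr1 families are uncertain, since the counting could have split or shared their reads. Hamp2 was at 8.22 without siCntrl 3, Inmt at 7.33 without siCntrl 3, Lox at −8.47 without siSTAT3 2, and Sprr1a at −7.58 without siSTAT3 1 and −9.75 without siSTAT3 2.

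Among drug-metabolising cytochrome P450 genes, 25 of 28 measured members were higher and 1 lower, 26 and 1 adjusted over the list alone (camera adjusted p = 1.78e-17, adjusted p = 0.0539 with an estimated correlation). Cyp1a2 (647 ± 109 against 4.97 ± 0.532 CPM), Cyp2c50 (log2 fold change 6.02 ± 0.42) and Cyp2a5 (5.57 ± 0.66) rose, and the lower member was Cyp1b1, a P450 gene with low expression in hepatocytes (−3.19 ± 0.55). For bile acid synthesis and transport, 19 of 23 measured members were higher and 1 lower, 19 and 1 adjusted over the list alone (camera adjusted p = 1.55e-10, adjusted p = 0.107 with an estimated correlation). The transporter genes Slco1b2 (3.49 ± 0.33) and Slc10a1 (2.57 ± 0.25) and the synthesis gene Cyp8b1 (3.30 ± 0.38) were higher, and Acox2 was lower (−1.35 ± 0.20). Pericentral hepatocyte genes, which share Cyp2e1 and Cyp1a2 with the P450 list and Cyp27a1 with the bile acid list, moved with them. In their list 13 of 15 measured members were higher and 1 lower, 13 and 1 adjusted over the list alone (camera adjusted p = 7.28e-10, adjusted p = 0.0270 with an estimated correlation). Glul, the glutamine synthetase gene, had a log2 fold change of 2.84 ± 0.27 and Lgr5, a receptor gene of Wnt signalling, one of 2.66 ± 0.56. Of periportal hepatocyte genes, 6 of 14 measured members were higher and 4 lower, 6 and 4 adjusted over the list alone (camera adjusted p = 0.109), with Ass1 of the urea cycle higher (2.76 ± 0.30) and Cdh1 lower (−2.33 ± 0.21). General hepatocyte markers rose as well, and 12 of 17 measured members were higher, 12 adjusted over the list alone (camera adjusted p = 1.22e-05, adjusted p = 0.3002 with an estimated correlation). Fah, an enzyme gene of tyrosine breakdown, had a log2 fold change of 3.04 ± 0.21. The hepatocyte marker list's 0 lower became 2 with library totals. Cyp2a5 was at 6.30 without siCntrl 3, and Lgr5 at 3.90 without siCntrl 2.

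Lipid and sugar genes moved in parts, in an arm where 45.7% of all tested genes were called. In fatty acid and triglyceride synthesis, 11 of 20 measured members were higher, 11 adjusted over the list alone (camera adjusted p = 4.28e-05, adjusted p = 0.178 with an estimated correlation), led by Thrsp (5.73 ± 0.47) and Mlxipl (2.49 ± 0.34), and Fasn was at 163 ± 42.8 against 48.6 ± 10.8 CPM. Of cholesterol synthesis genes, 11 of 25 measured members were higher and 9 lower, 11 and 9 adjusted over the list alone (camera adjusted p = 0.437), and its median of 0.02 changed sign under library totals. Insig1 (2.34 ± 0.31) and Tm7sf2 (1.99 ± 0.21) were among the higher members and Sqle (−1.88 ± 0.42) among the lower. Of fatty acid oxidation genes and targets of the receptor PPARA, 7 of 27 measured members were higher and 7 lower, 7 and 7 adjusted over the list alone (camera adjusted p = 0.673), with Acot3 higher (3.30 ± 0.49) and the lipid droplet genes Cidec (−4.44 ± 0.47) and Plin2 (−3.29 ± 0.25) lower. In glucose metabolism, 8 of 16 measured members were higher and 1 lower, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00256, adjusted p = 0.303 with an estimated correlation). The glycogen synthase gene Gys2 (2.63 ± 0.26) and the glycogen phosphorylase gene Pygl (1.65 ± 0.18) rose, and Igfbp1 fell (−3.95 ± 0.97). Genes of NRF2, a regulator of antioxidant defence, and of oxidative stress went both ways: 11 of 20 measured members were higher and 4 lower, 11 and 4 adjusted over the list alone (camera adjusted p = 0.00337, adjusted p = 0.303 with an estimated correlation). Sod1, a superoxide dismutase gene, was higher (1.35 ± 0.17) and Slc7a11, a cystine transporter gene, lower (−2.72 ± 0.72). The fatty acid synthesis list's 0 lower became 2 with library totals. The cholesterol synthesis list's 11 higher became 6 with library totals. The fatty acid oxidation list's 7 higher became 3 with library totals, and its 7 lower became 13 with library totals. The NRF2 list's 4 lower became 7 with library totals. Igfbp1 was at −4.62 without siSTAT3 3.

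Matrix genes fell nearly as a whole. Of the fibrosis and extracellular matrix list, 35 of 36 measured members were lower, 35 adjusted over the list alone (camera adjusted p = 1.13e-16, adjusted p = 0.172 with an estimated correlation). Col1a1, a chain of type I collagen, stood at 29.4 ± 2.18 against 348 ± 102 CPM, Timp1, an inhibitor of matrix proteases, at 0.791 ± 0.260 against 20.6 ± 6.43 CPM, and Col3a1 had a log2 fold change of −2.30 ± 0.38. Among stellate cell and myofibroblast markers, 8 of 16 measured members were lower and 2 higher, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0178, adjusted p = 0.463 with an estimated correlation). The contractile genes Acta2 (−6.71 ± 0.29), Tagln (−5.07 ± 0.23) and Myl9 (−3.49 ± 0.24) fell, and so did the growth factor receptor gene Pdgfrb (−1.82 ± 0.21). For cholangiocyte and progenitor markers, 7 of 11 measured members were lower and 1 higher, 9 and 1 adjusted over the list alone (camera adjusted p = 9.18e-04, adjusted p = 0.172 with an estimated correlation), including Krt8 (−3.02 ± 0.20) and Sox9 (−1.65 ± 0.26). The higher member was the keratin gene Krt23 (2.26 ± 0.63). The call of Krt23 ended without siCntrl 1 (edgeR adjusted p = 0.0509), with no filter (0.0504) and with voom (0.0514), with a range of 0.00147 to 0.0514 over alternatives. The stellate list's 2 higher became 4 without siSTAT3 2 and 0 with library totals.

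Markers of other cell types moved beside the matrix genes. Of monocyte and scar-associated macrophage markers, 10 of 12 measured members were lower, 10 adjusted over the list alone (camera adjusted p = 4.28e-05, adjusted p = 0.220 with an estimated correlation). F13a1 (−5.24 ± 0.62), Itgam (−3.07 ± 0.29) and Lgals3 (−3.23 ± 0.35) fell. Neutrophil markers fell in part, and 6 of 13 measured members were lower, 6 adjusted over the list alone (camera adjusted p = 0.0178, adjusted p = 0.506 with an estimated correlation). Cxcr2 was among them (−3.57 ± 0.50). Kupffer cell and macrophage markers gave 6 of 14 measured members lower and 1 higher, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0635), with Marco (−2.93 ± 0.54) and Cd68 (−2.44 ± 0.19) lower. Of sinusoidal endothelial markers, 8 of 15 measured members were lower, 8 adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.506 with an estimated correlation), such as Lyve1 (−1.77 ± 0.47) and Tek (−1.14 ± 0.30). Lymphoid markers gave few calls. Of T and NK cell markers 1 of 14 was higher (Nkg7) and 2 were lower (Cd3e and Cd8b1), and adjusted over the list alone the count was 0, against 4 at an unadjusted p under 0.05, 4 by DESeq2 and 2 by voom (camera adjusted p = 0.949). Their calls ended when 1 library was left out, with edgeR adjusted p = 0.122 for Nkg7 and 0.0954 for Cd8b1 without siCntrl 1, 0.121 for Nkg7 without siCntrl 2, 0.149 for Cd3e without siCntrl 3, 0.0781 for Cd8b1 without siSTAT3 1, 0.0699 for Cd3e and 0.0600 for Nkg7 without siSTAT3 2, and 0.103 for Nkg7 without siSTAT3 3. The call of Nkg7 also ended with no filter, over the compared libraries alone, with library totals and after thinning. That of Cd8b1 ended with voom. Over all alternatives the edgeR, DESeq2 or voom adjusted p ran from 0.00754 to 0.176 for Nkg7, 0.00422 to 0.0954 for Cd8b1 and 0.00515 to 0.149 for Cd3e. Of 13 B and plasma cell markers 0 passed edgeR's test over all genes or over the list alone, against 2 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom (camera adjusted p = 0.490). The medians of the lymphoid lists, 0.02 and 0.29, changed sign under library totals, and the mean of the T and NK list and its test lay below 0. The Kupffer list's 6 lower became 3 without siCntrl 2 or siSTAT3 1 or 2. The sinusoidal endothelial list's 8 lower became 3 without siCntrl 2 or siSTAT3 2, 5 without siCntrl 3 and 4 without siSTAT3 1. The T and NK list's 2 lower became 0 of 3 left with the stricter filter. The B and plasma list's 0 higher became 2 without siCntrl 2, and its 0 lower became 2 without siCntrl 1 or by DESeq2 and 3 with library totals. Cd3e was at −1.13 without siCntrl 3, and Cd8b1 at −1.77 without siCntrl 1.

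Acute phase genes, which hepatocytes express in response to interleukin 6, fell in part: 13 of 26 measured members were lower and 3 higher, 13 and 3 adjusted over the list alone (camera adjusted p = 0.00504, adjusted p = 0.463 with an estimated correlation). Saa1 (59.1 ± 17.98 against 8327 ± 4138 CPM), Lcn2 (−5.52 ± 0.52) and Orm2 (−3.77 ± 0.66) were lower and Saa4 higher (1.76 ± 0.15). For STAT3 targets and interleukin 6 feedback genes, 12 of 22 measured members were lower and 2 higher, 12 and 2 adjusted over the list alone (camera adjusted p = 0.00999, adjusted p = 0.436 with an estimated correlation). Osmr (−1.87 ± 0.24) and Fos (−2.77 ± 0.74) were lower and Vegfa higher (1.34 ± 0.20). Of JAK-STAT components, 4 of 19 measured members were higher and 3 lower, 4 and 3 adjusted over the list alone (camera adjusted p = 0.783), with Socs2 the highest (1.76 ± 0.24). Among inflammatory cytokine and NF-kB genes, 10 of 19 measured members were lower, 11 adjusted over the list alone (camera adjusted p = 8.90e-04, adjusted p = 0.340 with an estimated correlation), the chemokine genes Ccl2 (−3.69 ± 0.56) and Ccl7 (−3.31 ± 0.82) included. Immediate early genes gave a like count, as 11 of 15 measured members were lower, 11 adjusted over the list alone (camera adjusted p = 7.60e-04, adjusted p = 0.340 with an estimated correlation), with Egr1 at −4.01 ± 0.35. In the interferon response, 13 of 33 measured members were higher, 13 adjusted over the list alone (camera adjusted p = 0.00337, adjusted p = 0.463 with an estimated correlation), Cxcl9 (2.31 ± 0.28) and Ifit1 (1.31 ± 0.25) among them, and the list's median of 0.50 changed sign under library totals. The acute phase list's 3 higher became 1 without siCntrl 1 or siSTAT3 2, with no filter or with library totals. The JAK-STAT list's 4 higher became 2 without siSTAT3 3, with no filter or with library totals, and its 3 lower became 5 without siCntrl 1 and 10 with library totals. The cytokine and NF-kB list's 10 lower became 16 with library totals. The interferon list's 13 higher became 6 with library totals, and its 0 lower became 6 with library totals. Orm2 was at −2.99 without siCntrl 2, Fos at −3.37 without siSTAT3 3, and Ccl7 at −4.37 without siSTAT3 3.

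Of the unfolded protein and integrated stress response list, 12 of 19 measured members were lower, 12 adjusted over the list alone (camera adjusted p = 1.93e-04, adjusted p = 0.172 with an estimated correlation). The serine synthesis genes Psat1 (0.685 ± 0.257 against 81.2 ± 12.3 CPM) and Phgdh (0.0565 ± 0.0767 against 7.502 ± 2.36 CPM) and the asparagine synthetase gene Asns (−4.34 ± 0.41) fell most, and the chaperone gene Hspa5 by less (−1.12 ± 0.24). For p53 targets and apoptosis, 13 of 18 measured members were lower and 1 higher, 14 and 1 adjusted over the list alone (camera adjusted p = 5.77e-04, adjusted p = 0.0900 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1a at 1.498 ± 0.736 against 68.0 ± 21.3 CPM and Bbc3 the higher member (1.84 ± 0.24). Of cell cycle genes, 15 of 30 measured members were lower, 16 adjusted over the list alone (camera adjusted p = 0.00219, adjusted p = 0.581 with an estimated correlation). The replication helicase genes Mcm5 (−3.57 ± 0.64) and Mcm6 (−3.97 ± 0.80) fell, as did the mitotic kinase gene Cdk1 (−1.57 ± 0.34). The cell cycle list's 15 lower became 7 without siCntrl 2 and 9 without siSTAT3 1. Phgdh was at −8.88 without siSTAT3 1, Mcm5 at −2.93 without siCntrl 2, and Mcm6 at −3.20 without siCntrl 2.

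Limma's camera test with a preset correlation called 25 of the 34 lists tested in the siRNA arm, 11 up and 14 down. Only pericentral hepatocyte genes held with an estimated correlation (camera adjusted p = 0.0270). Fry, which asks only whether a list's genes move one way on balance, called 26 of the 34 after adjustment. Other splits of the same 6 libraries gave 10 to 23 camera calls of lists with the preset correlation. Each of these splits placed 1 or 2 libraries labelled siSTAT3 in each group, so part of the labelled difference stayed in them. They cannot show how many calls chance would give. A single list call carries little weight there, since only 1 camera call held with an estimated correlation.

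In the mASO arm, libraries labelled mASO STAT3 had more mRNA of most P450 and bile acid genes measured than mASO Scrbl, and less of most extracellular matrix genes. Cyp7a1 stood at 236 ± 120.1 against 0.315 ± 0.218 CPM (SD, n = 3), Cyp2e1 at 9447 ± 661 against 64.6 ± 28.2 CPM and Slc1a2 at 101 ± 11.96 against 0.256 ± 0.103 CPM. Acta2 stood at 1.38 ± 0.397 against 120.4 ± 25.0 CPM and Col1a1 at 33.3 ± 7.16 against 303 ± 182 CPM. By edgeR's test 3344 genes were higher and 3542 lower of 15720, 1825 and 1841 of them by more than 2-fold. Together 43.8% of all tested genes were called, the share against which member counts of lists in this arm are to be read. Scaled by library totals, 1525 were higher and 7939 lower, so that 16.1% of the calls were higher in place of 48.6%. Stat3 does not check the labels of this arm either. Cyp7a1 was at 10.23 without mASO Scrbl 3, and Col1a1 at −2.58 without mASO Scrbl 3.

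Upp2 (615 ± 239.6 against 2.17 ± 0.495 CPM), Serpina6 (1063 ± 153 against 5.84 ± 1.80 CPM), Hamp2 (log2 fold change 7.08 ± 0.73) and Cyp3a16 (7.74 ± 0.59) were again among the 10 highest. They were joined by 2810007J24Rik (432 ± 115 against 3.47 ± 0.857 CPM) and Csrp3, a muscle LIM protein gene (21.1 ± 3.84 against 0.179 ± 0.0969 CPM). Glns-ps1, a glutamine synthetase pseudogene with 3 counts over the control group, stood at 3.21 ± 3.46 CPM in mASO STAT3, with 364 of its 475 counts there in mASO STAT3 2. Its ratio of 272 (counting interval 92.6 to 1325) became 101 (33.6 to 496) without that library and 415 (141 to 2018) without mASO STAT3 3. Its reads could come from Glul, and voom did not call it (adjusted p = 0.0552). Psat1 (0.636 ± 0.0505 against 100.2 ± 16.8 CPM), Gprc5a (0.0473 ± 0.0198 against 11.6 ± 1.28 CPM) and Sprr1a (−8.22 ± 0.92) were among the 10 lowest. No count of Cdh17 or Hemt1 was seen in mASO STAT3 libraries, and these were at least 451 and 128-fold lower by the floor of 3 counts over the group. With 1 or 2 counts in the group, ratios of control to mASO STAT3 were 613 for Gm8818 (109.8 to 24235), 475 for Gml (84.9 to 18768), 386 for Nefl (69.0 to 15253), 292 for Sprr1b (52.2 to 11555) and 255 for 1700016C15Rik (70.5 to 2112). By the rule for named genes all 20 had to pass edgeR's test, and their adjusted p ran up to 7.83e-04. Without mASO STAT3 2 the bounds were 285 and 81.0-fold for Cdh17 and Hemt1, and the ratios 299.9 (53.7 to 11861) for Gml, 185 (33.0 to 7302) for Sprr1b and 161 (44.5 to 1334) for 1700016C15Rik. No count of Gm8818 or Nefl was left then, and they were at least 129 and 81.2-fold lower. Without mASO STAT3 3 the bounds were 294 and 83.6-fold and the ratios 399.9 (71.6 to 15809.9) for Gm8818, 252 (45.0 to 9950.4) for Nefl and 167 (46.0 to 1378) for 1700016C15Rik. No count of Gml or Sprr1b was left then, and they were at least 103 and 63.5-fold lower. Without mASO STAT3 1 no count of 1700016C15Rik was left (at least 122-fold), and without mASO Scrbl 3 the ratio of Gm8818 was 336 (60.0 to 13312). Hamp2 was at 6.40 without mASO STAT3 1 and 7.71 without mASO Scrbl 3, Cyp3a16 at 8.61 without mASO Scrbl 3, and Sprr1a at −9.04 without mASO STAT3 3 and −7.56 without mASO Scrbl 3.

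Of drug-metabolising P450 genes, 25 of 28 measured members were higher and 1 lower, 26 and 1 adjusted over the list alone (camera adjusted p = 4.93e-16, adjusted p = 0.0628 with an estimated correlation), with Cyp2a5 at 4.69 ± 0.63 and Cyp1a2 at 5.38 ± 0.38. In bile acid synthesis and transport, 20 of 23 measured members were higher and 1 lower, 20 and 1 adjusted over the list alone (camera adjusted p = 6.70e-12, adjusted p = 0.0961 with an estimated correlation), with Cyp8b1 at 4.49 ± 0.41, Slco1b2 at 4.11 ± 0.34 and Acox2 lower (−0.87 ± 0.20). Pericentral hepatocyte genes rose, since 13 of 15 measured members were higher, 13 adjusted over the list alone (camera adjusted p = 4.92e-11, adjusted p = 0.0104 with an estimated correlation), with Glul at 3.78 ± 0.29 and Lgr5 at 4.75 ± 0.63. Periportal hepatocyte genes gave 9 of 14 measured members higher and 3 lower, 10 and 4 adjusted over the list alone (camera adjusted p = 0.0324, adjusted p = 0.485 with an estimated correlation). Their list call ended without mASO STAT3 3 (camera adjusted p = 0.0549, range over alternatives 0.00918 to 0.485). Ass1 (2.72 ± 0.30) and Gls2 (3.02 ± 0.35) rose, and Apoa4 fell (−2.30 ± 0.36). Among general hepatocyte markers, 14 of 17 measured members were higher, 14 adjusted over the list alone (camera adjusted p = 1.61e-07, adjusted p = 0.213 with an estimated correlation), with Fah at 3.07 ± 0.21 and Apoa1 at 1.61 ± 0.25. Cyp2a5 was at 5.41 without mASO Scrbl 3.

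In cholesterol synthesis, 19 of 25 measured members were higher, 19 adjusted over the list alone (camera adjusted p = 1.55e-07, adjusted p = 0.406 with an estimated correlation), with Insig1 at 3.18 ± 0.32 and Tm7sf2 at 2.40 ± 0.21. In fatty acid and triglyceride synthesis, 16 of 20 measured members were higher, 17 adjusted over the list alone (camera adjusted p = 1.40e-07, adjusted p = 0.125 with an estimated correlation), with Thrsp at 5.62 ± 0.47 and Fasn at 387 ± 90.9 against 65.4 ± 15.8 CPM. Fatty acid oxidation genes and PPARA targets gave 11 of 27 measured members higher and 5 lower, 11 and 5 adjusted over the list alone (camera adjusted p = 0.0765), and their median of 0.31 changed sign under library totals. Acot3 was higher (3.19 ± 0.49) and Cidec lower (−4.65 ± 0.47). For glucose metabolism, 11 of 16 measured members were higher and 1 lower, 11 and 2 adjusted over the list alone (camera adjusted p = 4.42e-04, adjusted p = 0.214 with an estimated correlation). G6pc, the glucose-6-phosphatase gene (3.19 ± 0.59), and Gys2 (2.75 ± 0.26) rose. Of NRF2 and oxidative stress genes, 11 of 20 measured members were higher and 5 lower, 11 and 7 adjusted over the list alone (camera adjusted p = 0.0733), with Sod1 higher (1.24 ± 0.17) and Slc7a11 lower (−3.31 ± 0.74). The cholesterol synthesis list's 19 higher became 12 with library totals, and its 0 lower became 2 with library totals. The fatty acid synthesis list's 16 higher became 9 with library totals. The fatty acid oxidation list's 11 higher became 6 with library totals, and its 5 lower became 3 without mASO Scrbl 2 and 8 with library totals. The NRF2 list's 5 lower became 8 with library totals. Acot3 was at 3.81 without mASO Scrbl 2, G6pc at 3.98 without mASO Scrbl 3, and Slc7a11 at −2.61 without mASO Scrbl 3.

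Of the fibrosis and extracellular matrix list, 28 of 36 measured members were lower, with 28 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.61e-11, adjusted p = 0.214 with an estimated correlation). Thbs1, which encodes the matrix protein thrombospondin, had a log2 fold change of −5.27 ± 0.40, and Lox one of −5.58 ± 0.39. Of stellate cell and myofibroblast markers, 6 of 16 measured members were higher and 5 lower, 7 and 5 adjusted over the list alone (camera adjusted p = 0.696). The contractile genes Acta2 (−6.45 ± 0.28), Tagln (−4.76 ± 0.23) and Myl9 (−4.02 ± 0.24) fell, and Reln, a gene of quiescent stellate cells, rose (1.10 ± 0.20). The median of that list was 0.11 and changed sign under library totals, and its mean was −0.63. Of cholangiocyte and progenitor markers, 7 of 11 measured members were lower, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00328, adjusted p = 0.213 with an estimated correlation), with Krt8 at −3.55 ± 0.20 and Cldn4 at −3.83 ± 0.68. The stellate list's 6 higher became 1 with library totals.

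Monocyte and scar-associated macrophage markers fell beside the matrix genes, and 7 of 12 measured members were lower, 7 adjusted over the list alone (camera adjusted p = 3.92e-04, adjusted p = 0.262 with an estimated correlation), with F13a1 at −3.20 ± 0.55 and Itgam at −2.31 ± 0.28. For neutrophil markers, 7 of 13 measured members were lower, 7 adjusted over the list alone (camera adjusted p = 0.0297, adjusted p = 0.590 with an estimated correlation), Mmp9 and Cxcr2 among them (−2.77 ± 0.53 and −2.98 ± 0.47). That list call ended without mASO Scrbl 1 (camera adjusted p = 0.136, range over alternatives 0.00115 to 0.590). Of Kupffer cell and macrophage markers, 2 of 14 were lower, Cd68 (−2.69 ± 0.19) and Marco (−2.39 ± 0.52), and 2 higher, Timd4 (0.98 ± 0.30) and Clec4f (0.92 ± 0.33), with 2 and 1 adjusted over the list alone (camera adjusted p = 0.715). Their median of 0.01 changed sign under library totals and their mean was −0.27. The edgeR call of Timd4 ended without mASO Scrbl 2 or 3 (adjusted p = 0.0714 and 0.0656, range over alternatives 0.00216 to 0.280). That of Clec4f ended without mASO STAT3 1, 2 or 3 (0.0954, 0.0715 and 0.0683) and without mASO Scrbl 2 or 3 (0.129 and 0.126). It also ended with no filter (0.116) and with a block for the replicate number (0.0619), with a range of 0.00351 to 0.397. Sinusoidal endothelial markers gave 3 of 15 measured members lower and 1 higher, 1 and 0 adjusted over the list alone (camera adjusted p = 0.715), with Lyve1 at −1.81 ± 0.47. Of T and NK cell markers, 6 of 14 measured members were higher, 6 adjusted over the list alone (camera adjusted p = 0.0281, adjusted p = 0.448 with an estimated correlation), with the granzyme gene Gzma at 1.82 ± 0.45. Without mASO Scrbl 2 the list had a camera adjusted p of 0.0622 (range over alternatives 0.0197 to 0.448). Of B and plasma cell markers, 6 of 13 measured members were higher, 6 adjusted over the list alone (camera adjusted p = 0.00826, adjusted p = 0.485 with an estimated correlation), Igha among them (1.73 ± 0.34). The neutrophil list's 7 lower became 4 with no filter and 3 without mASO STAT3 1 or 3 or mASO Scrbl 1. The Kupffer list's 2 higher became 0 without mASO Scrbl 2 or 3 or with library totals, and its 2 lower became 4 over the compared libraries alone and 5 with library totals. The sinusoidal endothelial list's 1 higher became 3 without mASO STAT3 3, and its 3 lower became 1 without mASO STAT3 1 or 3 or mASO Scrbl 1 or 3 and 6 with library totals. The T and NK list's 6 higher became 1 of 3 left with the stricter filter, 3 without mASO Scrbl 2 and 1 with library totals. The B and plasma list's 6 higher became 1 without mASO STAT3 1 or with library totals and 2 without mASO Scrbl 1 or 2. Marco was at −1.65 without mASO Scrbl 1.

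Among acute phase genes, 5 of 26 measured members were lower and 4 higher, 5 and 4 adjusted over the list alone (camera adjusted p = 0.993). Saa1 stood at 68.7 ± 29.6 against 1044 ± 861 CPM and Lcn2 had a log2 fold change of −3.26 ± 0.47, while Saa4 was higher (2.21 ± 0.16). The list's median was −0.14 and its mean −0.39, and its test pointed up. Of STAT3 targets and interleukin 6 feedback genes, 9 of 22 measured members were lower and 2 higher, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0324, adjusted p = 0.506 with an estimated correlation), with Timp1 (−3.41 ± 0.36) and Junb (−2.26 ± 0.22) lower and Vegfa higher (1.40 ± 0.20). The call of that list ended without mASO Scrbl 1 (camera adjusted p = 0.0527, range over alternatives 0.0143 to 0.506). For JAK-STAT components, 5 of 19 measured members were higher and 5 lower, 5 and 5 adjusted over the list alone (camera adjusted p = 0.813), with Lifr at 1.52 ± 0.23 and Osmr at −1.80 ± 0.24. Of inflammatory cytokine and NF-kB genes, 8 of 19 measured members were lower, 8 adjusted over the list alone (camera adjusted p = 0.0196, adjusted p = 0.506 with an estimated correlation), with Cd14 at −3.63 ± 0.26 and Ccl2 at −3.49 ± 0.55. Of immediate early genes, 9 of 15 measured members were lower, 9 adjusted over the list alone (camera adjusted p = 0.00530, adjusted p = 0.485 with an estimated correlation), with Egr1 at −3.71 ± 0.35 and Fosb at −4.39 ± 0.89. In the interferon response, 9 of 33 measured members were lower and 8 higher, 9 and 8 adjusted over the list alone (camera adjusted p = 0.715), with Isg15 (−2.08 ± 0.30) and Irf7 (−1.31 ± 0.19) lower and Psmb8 (1.16 ± 0.17) and Cxcl9 (1.85 ± 0.27) higher. The acute phase list's 4 higher became 7 by DESeq2 and 1 with library totals, and its 5 lower became 14 with library totals. The STAT3 target list's 9 lower became 14 with library totals. The JAK-STAT list's 5 higher became 2 with library totals, and its 5 lower became 3 without mASO STAT3 1 or 3 or mASO Scrbl 1, with no filter or with a replicate block, 2 without mASO Scrbl 2 and 10 with library totals. The interferon list's 8 higher became 5 without mASO STAT3 3 or mASO Scrbl 2 and 2 with library totals, and its 9 lower became 17 with library totals. Saa1 was at −3.19 without mASO Scrbl 2, Ccl2 at −4.07 without mASO STAT3 3, and Fosb at −5.29 without mASO STAT3 3 and −3.67 without mASO Scrbl 3.

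Of the unfolded protein and integrated stress response list, 10 of 19 measured members were lower and 1 higher, 14 and 2 adjusted over the list alone (camera adjusted p = 9.08e-04, adjusted p = 0.213 with an estimated correlation), with Phgdh at −5.26 ± 0.56 and Asns at −3.91 ± 0.39. For p53 targets and apoptosis, 9 of 18 measured members were lower and 1 higher, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00530, adjusted p = 0.125 with an estimated correlation), with Cdkn1a at −3.91 ± 0.41 and Bbc3 higher (1.996 ± 0.24). Cell cycle genes were lower where they passed, and 15 of 30 measured members were lower, 15 adjusted over the list alone (camera adjusted p = 3.92e-04, adjusted p = 0.604 with an estimated correlation), with Mcm5 at −3.71 ± 0.63 and Top2a at −2.86 ± 0.69. In this arm camera called 21 of 34 lists, 11 up and 10 down. Pericentral hepatocyte genes alone held with an estimated correlation (camera adjusted p = 0.0104). Fry called 22 of the 34 after adjustment. Other splits of the 6 libraries gave 11 to 21 camera calls of lists, and they too keep part of the labelled difference. The unfolded protein list's 10 lower became 17 with library totals. The p53 and apoptosis list's 9 lower became 15 with library totals. The cell cycle list's 15 lower became 23 with library totals. Mcm5 was at −2.91 without mASO Scrbl 3, and Top2a at −1.91 without mASO Scrbl 3.

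**Figure D2:**
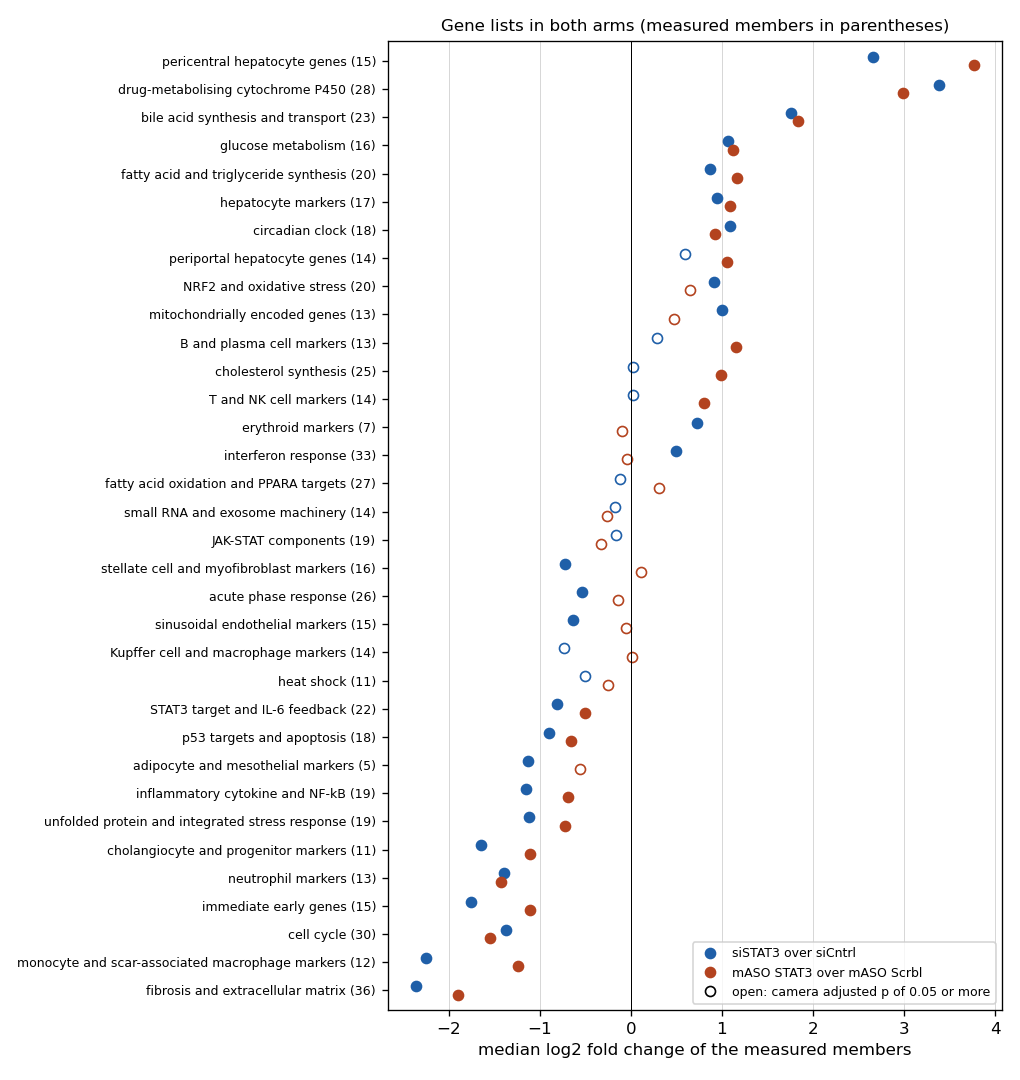
Median log2 fold change of the 34 tested gene lists in the siRNA arm and in the mASO arm. Open points mark lists with a camera adjusted p of 0.05 or more. The P450 list has medians of 3.38 and 2.99 and the fibrosis list −2.36 and −1.90, and medians that change sign under library totals are those of the T and NK, B and plasma, cholesterol and interferon lists in the siRNA arm and of the stellate, Kupffer, fatty acid oxidation and mitochondrial lists in the mASO arm.

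Across the arms, the libraries labelled STAT3 differed from their controls in like ways. Of 15720 genes, 2734 were higher in both arms, where independent lists would share 748, and 2657 were lower in both, where they would share 828. Only 7 of the 5398 genes called in both arms went opposite ways. The log2 fold changes of the arms correlated across genes with Pearson's r = 0.864 and Spearman's rho = 0.839, genes not being independent replicates, and 84.1% of genes had the same sign. The arms share no library. Over both arms, a comparison chosen after the data were seen, 4412 genes were higher and 4855 lower in the libraries labelled STAT3.

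**Figure D3:**
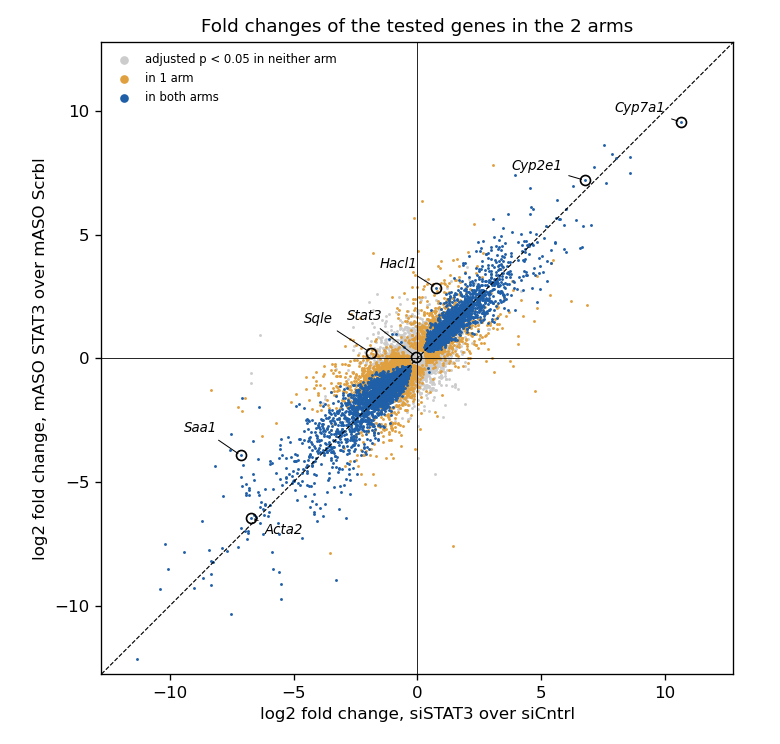
Log2 fold change of 15720 genes in the siRNA arm (x axis) and the mASO arm (y axis), with genes past edgeR's threshold in both arms in blue, in 1 arm in orange and in neither in grey. Points gather along the dashed line of equality (r = 0.864), with Cyp7a1 at 10.66 and 9.55 and Acta2 at −6.71 and −6.45, while Stat3 lies at −0.03 and 0.05.

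Hacl1, which encodes an enzyme of fatty acid alpha-oxidation, was the 1 gene whose change differed between the arms by edgeR's test. It stood at 385 ± 83.4 CPM in mASO STAT3 and 53.7 ± 2.45 CPM in mASO Scrbl, and at 205 ± 10.3 CPM in siSTAT3 and 121 ± 28.4 CPM in siCntrl (SD, n = 3). Its log2 fold change was 2.84 in the mASO arm and 0.76 in the siRNA arm, a difference of 2.08 ± 0.26 (edgeR adjusted p = 0.0216). The call ended without siSTAT3 2 or 3 (edgeR adjusted p = 0.0904 and 0.0924), mASO STAT3 3 (0.0528) or mASO Scrbl 2 or 3 (0.128 and 0.0907). It also ended with a block for the replicate number (0.129), where no gene passed. Over the alternatives the range was 1.95e-10 to 0.129. At an unadjusted p under 0.05 there were 1161 genes, and DESeq2 called 62 and voom 2. Without 1 library edgeR called 5 genes (siCntrl 1), 8 (siCntrl 2), 2 (siCntrl 3 or mASO Scrbl 1), 6 (siSTAT3 1) or 0 (the 5 libraries that end the call of Hacl1). No gene differed between mASO STAT3 and siSTAT3 by edgeR's test, a comparison chosen after the data were seen, against 919 at an unadjusted p under 0.05, 79 by DESeq2 and 0 by voom. Without siSTAT3 1 or mASO STAT3 3, edgeR called 5 genes there.

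Between the controls, mASO Scrbl livers had less Saa3, an acute phase gene, than siCntrl livers. It stood at 106 ± 46.7 CPM in mASO Scrbl and 3044 ± 2325 CPM in siCntrl (SD, n = 3), a log2 fold change of −4.84 ± 0.57 (edgeR adjusted p = 0.0260). The pseudogene Ppp1r2-ps4 stood at 0.114 ± 0.0298 and 3.86 ± 0.439 CPM (−5.06 ± 0.56, edgeR adjusted p = 0.00578), and its reads could be shared with its parent gene. These 2 were the genes called, against 1234 at an unadjusted p under 0.05, 79 by DESeq2 and 2 by voom. The call of Saa3 ended with no filter (edgeR adjusted p = 0.101), with the replicate block (0.102) and over the compared libraries alone (0.173). It also ended without siCntrl 2 (edgeR adjusted p = 0.0561) or mASO Scrbl 1, 2 or 3 (0.107, 0.0925 and 0.0856), with a range of 5.41e-15 to 0.173 over the alternatives. The call of Ppp1r2-ps4 ended without mASO Scrbl 2 (0.0527, range 4.72e-19 to 0.0527). EdgeR called 13 genes without siCntrl 1, 4 without mASO Scrbl 1, 0 without mASO Scrbl 2 and 1 without mASO Scrbl 3. The acute phase list as a whole had a median of −0.90 between the controls (camera adjusted p = 4.90e-28, adjusted p = 0.0992 with an estimated correlation), and limma's fry test gave an adjusted p of 0.0145. Camera called 20 of 34 lists between the controls, and 0 of the calls held with an estimated correlation, where fry called 4 at an unadjusted p under 0.05. The labels give no sequencing run, so a difference between runs and one between arms cannot be told apart. Saa3 was at −4.05 without siCntrl 3.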

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

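The tests of lists on the difference between the arms, with a preset or an estimated correlation, were chosen after the results of each arm were seen, while leaving out each library was planned. Hacl1, the fatty acid alpha-oxidation gene, changed by 2.08 more on the log2 scale in the mASO arm than in the siRNA arm, and stands out because edgeR's test of that difference passed. Over 50 splits that redrew the arm labels, 12 gave as many genes as the real count of 1, and the highest other gave 373, so chance is not excluded and the 373 point to a structure of the samples, not identified here. Camera called 21 of 34 lists for the difference, 0 of the calls held with an estimated correlation, and fry called 0 after adjustment and 6 at an unadjusted p under 0.05. The 6 lists with both a camera adjusted p and a fry p under 0.05 are given here. Stellate cell and myofibroblast markers had a median difference of 0.57, camera adjusted p = 1.03e-05, adjusted p = 0.290 with an estimated correlation, fry adjusted p = 0.234. T and NK cell markers had a median difference of 0.97, camera adjusted p = 5.71e-05, adjusted p = 0.290 with an estimated correlation, fry adjusted p = 0.175. P53 targets and apoptosis genes had a median difference of 0.11, camera adjusted p = 0.0428, adjusted p = 0.290 with an estimated correlation, fry adjusted p = 0.234.

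Acute phase, cholesterol synthesis and interferon response genes were the lists that separated the arms most by camera. Acute phase genes had a median difference of 0.71 (camera adjusted p = 3.32e-14), cholesterol synthesis genes one of 1.16 (2.01e-22) and interferon response genes one of −0.68 (2.70e-13), each with adjusted p = 0.280 with an estimated correlation and a fry adjusted p of 0.175. Leaving out each of the 12 libraries kept call and direction in 36 of 36 fits, so no 1 library decided the camera calls with the preset correlation. Since the 3 lists had the smallest camera p in the same data, that outcome was likely beforehand. None of the 3 passed with an estimated correlation, so correlated members may account for the camera calls. The acute phase difference lay between the controls (median −0.90) more than between the STAT3 groups (−0.06), the cholesterol difference between the STAT3 groups (0.88) more than between the controls (−0.28), and the interferon difference between the controls (0.44) more than between the STAT3 groups (−0.21). A difference between sequencing runs cannot be told apart from the arm, since the labels give no run, and a biological difference between the 2 kinds of load stays open, untested.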

How the results depend on the processing

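Library totals, thinning and the comparison of the STAT3 groups were chosen after the data were seen, the other alternatives given here before. Scaled by library totals, 1655 genes were higher and 7266 lower in the siRNA arm and 1525 and 7939 in the mASO arm, the controls differed in 5 genes, and the log2 fold change of Stat3 was −0.54 and −0.53, because that scaling drops the composition factor. For the difference of the arms edgeR called 3 genes with no filter, 2 with the stricter filter and 0 with the replicate block, DESeq2 62 and voom 2, and 0 to 8 were called without 1 library. Between the controls there were 7 with no filter, 79 by DESeq2 and 0 to 13 without 1 library, and between the STAT3 groups 6, 79 and 0 to 5; the cause was not tested. With an estimated correlation 1 list was called in each arm. Without 1 library, Stat3 ranged from −0.12 to 0.0823 in the siRNA arm and −0.0420 to 0.15 in the mASO arm, turning sign without siCntrl 2 (0.0181), siSTAT3 1 (0.0823), mASO STAT3 3 (−0.0420) or mASO Scrbl 2 (−0.0159), and passed in no such fit; counts were 2934 to 3267 higher and 3046 to 3400 lower in the siRNA arm and 2819 to 3121 and 2839 to 3103 in the mASO arm, lists 23 to 27 and 19 to 23, and Pearson's r across genes 0.815 to 0.857. Among the named genes, between 353 of 404 and 380 of 410 kept both without 1 library. Of 811 named results, Stat3 not counted, 806 kept direction and side of the threshold with DESeq2's size factors, 746 with no filter, 787 with DESeq2, 772 with voom, 764 with the block, 762 of 804 over the compared libraries alone, 779 of 783 with the stricter filter, and 668 with library totals (98 no longer passed, 20 newly passed, 25 turned). Under library totals Stat3 turned from 0.05 to −0.53 in the mASO arm and passed (edgeR adjusted p = 0.00413), and in the siRNA arm it newly passed (0.00446). That scaling also turned, without a call, the siRNA arm log2 fold change of Lbp (−0.0588), Stat5b (−0.13), Hlf (−0.0965), mt-Nd1 (−0.0223) and Ago3 (−0.00689), and the mASO arm one of Crp (−0.15), Stat5b (−0.0900), Stat2 (−0.0165), Stat5a (−0.10), Col14a1 (−0.21), Serpina1a (−0.00859), Msln (−0.30), Slc25a1 (−0.19), Acadm (−0.0666), Slc25a20 (−0.14), Cpt2 (−0.0983), Cpt1a (−0.0330), Gsta4 (−0.12), Atf4 (−0.15), Herpud1 (−0.12), Nr1d2 (−0.0244), Hlf (−0.22), mt-Nd4 (−0.0159), mt-Co1 (−0.11) and mt-Nd6 (−0.20). Msln also turned without mASO STAT3 2 (range −0.33 to 0.55 without 1 library) and Alas2 without mASO Scrbl 2 (−0.34 to 0.0152), neither past the threshold; the cause was not tested. After thinning, 795 of 808 were kept, so depth limits few of these calls.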

Other observations

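Clock genes, which drive daily cycles of transcription, differed in both arms, in tests planned before the data were examined. In the siRNA arm 12 of 18 measured members were higher and 3 lower, 12 and 4 adjusted over the list alone (camera adjusted p = 9.18e-04, adjusted p = 0.120 with an estimated correlation), and in the mASO arm 12 of 18 measured members were higher and 3 lower, 12 and 4 adjusted over the list alone (camera adjusted p = 0.00452, adjusted p = 0.164 with an estimated correlation). The activator genes Npas2 (−4.06 ± 0.65 and −3.13 ± 0.61 in the siRNA and mASO arm) and Clock (−1.52 ± 0.28 and −1.15 ± 0.28) were lower, and Per3 (2.55 ± 0.30 and 1.93 ± 0.29), Dbp (2.33 ± 0.27 and 1.41 ± 0.26) and Usp2 (3.40 ± 0.40 and 2.69 ± 0.38) higher. Of small RNA and exosome machinery genes, 6 of 14 measured members were lower and 3 higher, 6 and 3 adjusted over the list alone in the siRNA arm (camera adjusted p = 0.109) and 6 of 14 measured members were lower and 1 higher, 6 and 1 adjusted over the list alone in the mASO arm (camera adjusted p = 0.0648). The tetraspanin genes Cd9 (−3.20 ± 0.17 and −3.39 ± 0.17) and Cd63 (−2.78 ± 0.22 and −2.69 ± 0.22), which other cell types of liver also express and the monocyte list also holds, fell. Heat shock genes gave 4 of 11 measured members lower and 1 higher, 4 and 1 adjusted over the list alone (camera adjusted p = 0.0799) and 4 of 11 measured members lower and 1 higher, 4 and 1 adjusted over the list alone (camera adjusted p = 0.492), with the chaperone gene Hsp90aa1 at −1.51 ± 0.21 and −1.13 ± 0.21. Without siSTAT3 2 the fold change of Npas2 moved by more than 1.5 times, to −5.03 in the siRNA arm. The small RNA and exosome list's 3 higher became 1 without siCntrl 2 or over the compared libraries alone and 0 without siSTAT3 2 or with library totals in the siRNA arm. The heat shock list's 4 lower became 9 with library totals in the siRNA arm. The clock list's 3 lower became 5 with library totals in the mASO arm. The small RNA and exosome list's 6 lower became 11 with library totals in the mASO arm. The heat shock list's 4 lower became 2 without mASO Scrbl 3 and 7 with library totals in the mASO arm.

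Of the genes encoded by mitochondrial DNA, 9 of 13 measured members were higher, 10 adjusted over the list alone in the siRNA arm (camera adjusted p = 0.00337, adjusted p = 0.463 with an estimated correlation), mt-Atp6 (2.36 ± 0.54) and mt-Co2 (2.21 ± 0.40) among them. In the mASO arm edgeR called 1 of 13 (mt-Nd4) and 0 over the list alone, against 3 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by voom (camera adjusted p = 0.122). The call of mt-Nd4 ended without mASO STAT3 1 (edgeR adjusted p = 0.0878), mASO STAT3 3 (0.0750), mASO Scrbl 1 (0.0897) or mASO Scrbl 2 (0.0822), with a range of 0.00274 to 0.936 over alternatives. The list's median of 0.47 in that arm changed sign under library totals. Erythroid markers gave 2 of 7 higher in the siRNA arm, 1 adjusted over the list alone (camera adjusted p = 0.0415, adjusted p = 0.463 with an estimated correlation), and 1 of 7 in the mASO arm (camera adjusted p = 0.696), where the median was −0.10 and the mean 0.95. The carbonic anhydrase gene Car1 was the member that passed over the list alone in both arms (5.63 ± 0.52 and 6.41 ± 0.54). The siRNA arm's list call ended without siCntrl 2 (camera adjusted p = 0.141) or siSTAT3 2 (0.0586), with a range of 0.0157 to 0.463 over alternatives. Of 5 adipocyte and mesothelial markers, 2 were lower in the siRNA arm, Fabp4 (−2.46 ± 0.25) and Wt1 (−2.06 ± 0.47), 2 adjusted over the list alone (camera adjusted p = 0.0319, adjusted p = 0.436 with an estimated correlation), and that call ended without siCntrl 3 (0.0553) or siSTAT3 2 (0.0992), with a range of 0.00936 to 0.436. In the mASO arm 1 of 5 was lower, Fabp4 (−1.71 ± 0.24), 1 adjusted over the list alone (camera adjusted p = 0.411). The pancreatic acinar and sex-linked lists had 1 measured member each and no list test. Cela1 rose by 1.65 ± 0.21 and 2.001 ± 0.21, and Xist by 1.03 ± 0.21 and 0.81 ± 0.21, which no longer passed under library totals (edgeR adjusted p = 0.0615 and 0.381, ranges over alternatives 1.28e-05 to 0.0615 and 5.82e-04 to 0.381). Fold changes moved by more than 1.5 times for mt-Atp6 without siSTAT3 3 (1.53) and Wt1 without siSTAT3 1 (−2.70) in the siRNA arm, and for Car1 without mASO Scrbl 3 (7.66) in the mASO arm. The mitochondrial list's 9 higher became 5 of 12 left over the compared libraries alone, 4 without siCntrl 2 or 3 or siSTAT3 1 or with library totals and 3 without siSTAT3 3 in the siRNA arm. The adipocyte and mesothelial list's 2 lower became 5 without siSTAT3 1 in the siRNA arm. The mitochondrial list's 1 higher became 3 without mASO STAT3 2, by DESeq2 or with a replicate block and 4 of 11 left over the compared libraries alone, and its 0 lower became 2 with library totals in the mASO arm. The erythroid list's 2 higher in the siRNA arm became 1 without siCntrl 1, 2 or 3 or siSTAT3 2, with no filter, with a replicate block or with library totals.

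The 3 tests on Stat3, the test on markers of other cell types and the splits within both arms were chosen after the results were seen, while thinning was added before its result was. Stat3 mRNA was not called lower in either arm relative to the composition-scaled level. The lower end of the 95% interval was −0.34 at its lowest (−0.336), far from the −1 of a halving, which argues against low precision at that scaling. That holds for Stat3 mRNA over all cells of a sample, since these libraries do not separate cell types. Under library totals, where Stat3 fell with the median of all genes, it stood at percentile 49.8 or higher among the fold changes of tested genes, which decides nothing, since scaling moves all genes of a library alike, so a fall shared with most genes stays open. Whether STAT3 activity fell stays open, since the STAT3 target list had a camera adjusted p of 0.436 at the smaller with an estimated correlation. Its medians were −0.81 and −0.50, and fry, which asks only about a shared direction, gave adjusted p = 0.00936 and 0.0137 in the siRNA and mASO arms. A change in protein, an earlier fall that had passed, or labels exchanged between whole groups could not be tested here. On the first principal component the controls lay at −81.1 to −65.4 and the libraries labelled STAT3 at 61.8 to 82.6. These values argue against single libraries exchanged between STAT3 and control.

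Most pericentral hepatocyte genes were higher and most matrix genes lower in both arms (matrix 35 and 28 of 36), and the matrix list did not pass with an estimated correlation (adjusted p = 0.172 and 0.214). Thinning every library to the same total kept 95.3% of the calls or more, which argues against depth. An equal loss of all cells other than hepatocytes would lower their markers alike. Yet 12 monocyte markers (mean log2 fold change −2.20 and −1.65) and 27 lymphoid markers (0.0171 and 1.048) moved apart. Two-sided permutation over genes gave p = 2e-05 in the siRNA arm and 1e-05, the smallest 100000 resamples can give, in the mASO arm. Genes are not independent replicates, so that p does not measure the spread between samples. Few T and NK markers passed the stricter filter, and Cd9 and Cd63 of the monocyte list are also expressed in other liver cell types. For these markers, the means argue against an equal loss as the whole source, while an unequal loss of cell types stays open. A change of expression within cells was not told apart from a change in cell numbers. The time of day of collection may contribute, given the clock genes. It stays open with the stage of any injury and the effect of the load itself, none of which the labels or Stat3 settle.

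Among the 10 splits of each arm, 1 gave as many genes as the real one in the siRNA arm (7190, highest other 1) and 1 in the mASO arm (6886, highest other 0). For lists the real counts were 25 (1 split, highest other 23) and 21 (2 splits, highest other 21), and for the controls 2 genes (3 splits, highest other 8). These splits are too few for a share under 0.05. Within each arm, the other splits mix STAT3 and control libraries and so keep part of the labelled difference. For the mean of both arms, with the load redrawn within each arm, 1 of 50 splits gave as many genes as the real 9267, with 2170 in the highest other. That share lies under 0.05, which argues against chance in how these libraries fell into groups for that count, without excluding it. A separate fit of 2 groups with no term for the arm gave 8914 genes. There 1 of 50 splits over the 12 libraries gave as many, with 0 in the highest other. That again argues against chance without excluding it, and other splits of both kinds can mix STAT3 and control libraries in a group. Chance differences between animals are not covered if the replicates of a group are technical. For differences of mean log2 CPM, the correlation between the arms across genes was 0.874, and at most 0.623 in absolute value in 81 pairs of other splits. Those splits also keep part of the labelled difference. Ppp1r2-ps4 was the 1 gene that differed between the arms over STAT3 and control libraries together by edgeR's test (−3.73 ± 0.37, adjusted p = 0.00171).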
